A study of Mus musculus with 22 samples.

How the data were processed

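Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in mpkCCD cells, clone 11, a mouse line of cortical collecting duct cells that responds to vasopressin. Cells were treated for 30 min with 0.1 nM dDAVP, an analog of vasopressin that acts on the V2 receptor, or with vehicle, per the labels' protocols. The antibodies were against the transcription factors CREB1 and C/EBP beta (gene Cebpb). The labels describe 22 samples. Of these, 12 were immunoprecipitated libraries: 4 of CREB1 after vehicle, 4 of CREB1 after dDAVP, and 2 of C/EBP beta per treatment. The other 10 were input libraries without antibody, and 2 of them were named for both antibodies, so that some experiments of the antibodies shared an input. Groups were taken from the sample titles. Whether replicates came from separate cultures was not stated beyond an experiment number.

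The deposited files were 4 peak lists, 1 per antibody and treatment. BWA, SAMtools, MACS2, bedtools and the mouse build mm10 were named in the submitters' processing notes, with no versions or roles. How the replicates were combined into a list was not given in the sources used here. The CREB1 lists held positions alone. The C/EBP beta lists also held a name and a score per peak. All C/EBP beta names were those of replicate 1 and carried the MACS2 settings of a bandwidth of 300, 1 duplicate kept and q of 0.01, per the names in the deposited lists. The score is the authors' own value for each replicate 1 peak, deposited without a stated scale. It was used to rank and filter peaks within a list. In 1 alternative for the peak counts, a lowest score of 42 was asked of both C/EBP beta lists. Whether scores are comparable between lists is unknown. CREB1 peaks were ranked by width, because those lists had no score. Some regions were very short, down to 3 bp in the C/EBP beta dDAVP list and 32 bp in the CREB1 dDAVP list, as parts of intersected regions would be, but no source states such a step.

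No read counts, signal tracks or peak lists of single replicates were analysed here. The sequencing depth behind each list is therefore unknown, and no test of the treatment over replicates could be made. A peak missing from a list was not called there, which does not show that the factor was absent. The number of peaks in a list depends on depth, on the yield of the immunoprecipitation and on how many replicates had to hold a peak. The p-values below describe these lists, with peaks or genes as units, and not the spread between cultures. Confidence intervals at 95% are Wilson intervals and cover the counting of peaks alone.

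Positions are given in mm10, counted from 1. Genes came from a RefSeq gene table of the same assembly, with 21631 protein-coding genes on 20 chromosomes (the autosomes and X). That table gave neither strand nor exons. The transcription start site foreseen in the plan was therefore replaced by either end of a protein-coding gene, and exons, introns and untranslated regions were not told apart. Distances run from the peak centre to the nearer gene end. A peak within 1000 bp counted as at a gene end, and a gene with a peak within 5000 bp as near a peak. The planned search for CRE and C/EBP motifs was not run, since it needs the genome sequence, which was not used here. The 2 peaks on unplaced contigs in each CREB1 list entered the counts and overlaps and no gene analysis.

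Peaks counted as shared when they overlapped by at least 1 bp. Overlaps were compared with 1000 random placements of the same widths on the same chromosomes, between the outermost genes, in a permutation test with one side; the smallest p it can give is 0.001. Shares of peaks at gene ends were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 comparisons. A set of 15 gene lists with 419 entries was written before the data were examined, and all entries were found in the gene table. Some genes are in several lists, such as Ddit3, Per1 and Ier2. Each list was tested in each of the 4 peak lists against all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 60 tests. Genes are not independent replicates. Adjusted p-values under 0.05 were called.

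The rule for named genes was also set before the data were examined. It took the gene nearest to the 8 best-ranked peaks of each peak list. It took up to 6 members per gene list and peak list, the closest first. It took up to 10 genes at peaks found in both treatments and up to 5 per treatment at peaks found in that treatment alone, all with a gene end within 1000 bp. Aqp2, Creb1, Cebpb, Crem, Fos, Nr4a1, Per1, Sgk1 and Scnn1a were named whatever their values. Alternatives covered the overlap that counts as shared, local placement within 50000 bp and the upper 50% of C/EBP beta peaks by score. They also covered the C/EBP beta dDAVP list cut by score to the length of the list it was compared with. Gene end distances of 500, 5000 and 50000 bp and genes of all types were used as well. Random gene ends and a smaller gene background were added after seeing the data.

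The procedures were tested on simulated data. Of 40 randomly placed lists with the widths of the CREB1 dDAVP list, set against C/EBP beta dDAVP peaks, 1 had a p of 0.05 or less. All 20 lists with 20 planted overlaps did. Of 50 simulated lists among 21631 genes with a planted share of 40% over a background of 5%, 46 were called, as were 7 of 587 lists with nothing planted. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.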

Results

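Binding sites of CREB1, the cAMP-responsive activator that protein kinase A phosphorylates, and of C/EBP beta, a leucine zipper factor of acute phase and stress responses, were mapped in mpkCCD collecting duct cells. The series was designed to find sites of both factors after 30 min of 0.1 nM dDAVP or vehicle. The CREB1 lists rested on 4 samples per treatment and the C/EBP beta lists on 2. The CREB1 list held 785 peaks after vehicle and 406 after dDAVP, which covered 238 kb and 104 kb. The C/EBP beta list held 209 peaks after vehicle and 2401 after dDAVP, which covered 49.0 kb and 660 kb. Median widths were 290, 250.5, 226 and 266 bp in that order. Each value below comes from a single pooled list per group, with no replicate error, and the read depth is unknown.

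The first comparison asked which CREB1 sites were found after dDAVP and after vehicle. CREB1 peaks stood at the immediate early gene Fos in both treatments, 116 bp from a gene end after vehicle and 132 bp after dDAVP. Pcna, the DNA polymerase clamp, and Ccna2, cyclin A2, also had a CREB1 peak in both lists. Peaks at Creb1 itself, at the clock gene Per1, at Junb and Ier2, and at the ER chaperone gene Hspa5 were in the vehicle list and not in the dDAVP list. A peak 24 bp from an end of Ppp1r15a, a phosphatase subunit of the stress response, was in the dDAVP list and not in the vehicle list.

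The CREB1 dDAVP list was almost entirely contained in the vehicle list. Of its 406 peaks, 398 overlapped a vehicle peak (98.0%, 95% interval 96.2 to 99.0), against a mean of 0.09 for random placements (permutation p = 0.001, the smallest possible). That p-value sets the lists against random positions and is no test of the treatment. In the other direction 397 of 785 vehicle peaks were shared (50.6%, 47.1 to 54.1) and 388 were not. Shared vehicle peaks were wider, with a median of 343 bp against 244 bp for the others. The shorter list is the one after dDAVP, so a peak missing there is not evidence that CREB1 left the site.

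Among CREB1 peaks found in both treatments, the widest at gene ends lay at Csnk1g2, a casein kinase, at Osbp, an oxysterol-binding protein, and at Trmt10a, a tRNA methyltransferase. The Csnk1g2 peak spanned 827 bp on chromosome 10 from 80621875 to 80622701 and ended inside the gene. The histone gene H4c1 on chromosome 13 had a peak of 593 bp after vehicle, from 23761130 to 23761722, and of 452 bp after dDAVP, the widest of that list. Other wide shared peaks were at BC005624, Oaz1, Trp53inp2, Tpr, Sf1 and Fam76b. A peak inside Rfx1, which encodes a regulatory factor X protein, lay 3057 bp from a gene end after vehicle and 3084 bp after dDAVP. Ranbp2, Esyt2, Fbxw7, Klc4 and Ddx49 were also among the widest peaks after dDAVP.

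Of the 388 CREB1 peaks in the vehicle list alone, the widest at gene ends were at Ubxn6 (511 bp), Ric8b (448 bp), Per1 (442 bp), Ndufb2 (421 bp) and Txn2 (399 bp). The Per1 peak spanned chromosome 11 from 69094786 to 69095227, over an end of the gene. Of the 8 peaks in the dDAVP list alone, the widest at gene ends were at Pak1ip1 (218 bp), Ppp1r15a (175 bp), Tmem167b (174 bp), Mmab (170 bp) and Babam2 (139 bp). These were all narrower than the list's median of 250.5 bp.

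**Figure D1:**
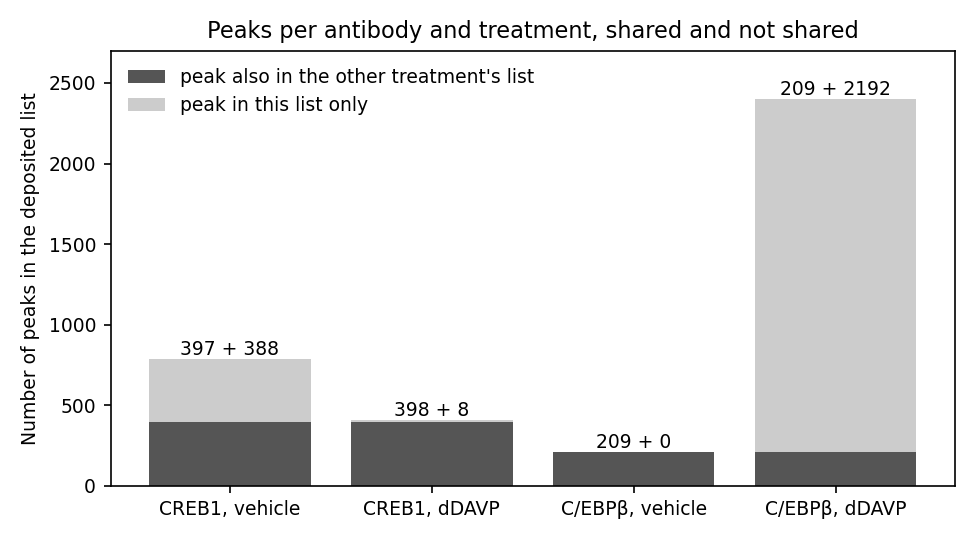
Bars show the number of peaks in each deposited list (vertical axis) for both antibodies and treatments, with peaks that overlap a peak of the other treatment in dark grey and the rest in light grey. The CREB1 dDAVP list has 8 peaks of its own and the C/EBP beta vehicle list has 0, while 388 CREB1 vehicle peaks and 2192 C/EBP beta dDAVP peaks are not shared.

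The same question was asked for C/EBP beta, where the longer list was the one after dDAVP. After dDAVP a peak lay 427 bp from an end of Aqp2, the vasopressin-regulated water channel, on chromosome 15 from 99584846 to 99585098, outside the gene. It lay past the gene's end with the higher coordinate, 99584545. Without strand, the start of a gene was not told apart from its other end. Further peaks absent from the vehicle list stood 259 bp from the end of Cebpb with the higher coordinate, inside that gene, and 272 bp from an end of Per1. Peaks at Ehf, an epithelial ETS factor, at Kcnj1, the renal potassium channel ROMK, at Trib1 and at Ddit3 (CHOP) were in both lists. The vehicle list had no C/EBP beta peak of its own.

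All 209 C/EBP beta vehicle peaks overlapped a dDAVP peak (100%, 98.2 to 100), against a mean of 0.13 for random placements (permutation p = 0.001, the smallest possible). As for CREB1, that p-value is no test of the treatment. In turn 209 of 2401 dDAVP peaks were shared (8.70%, 7.64 to 9.90) and 2192 were not. The dDAVP list was thus 11.5 times as long as the vehicle list, while the CREB1 dDAVP list was 0.517 times as long as its vehicle list. Shared C/EBP beta peaks had a median deposited score of 1104 in the dDAVP list, against 179 for the others. With the dDAVP list reduced to its 209 best scores, 153 of 209 vehicle peaks (73.2%) remained shared.

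The best-scoring C/EBP beta peak was the same site in both lists, inside Cdkl4, a kinase gene, on chromosome 17 from 80560619 to 80561194 in the dDAVP list. It scored 3880 there and 806 in the vehicle list. Peaks near Rcn1, Cotl1 and Abhd11 were also among the 8 best in both lists. The Cotl1 and Abhd11 peaks lay 89 and 84 bp from a gene end after dDAVP, and the Rcn1 peak lay outside the gene, 29025 bp away. The remaining best-ranked sites were near Ptpn12, Dynlt1b, Sytl3 and Smarca2 after vehicle, and near Btbd19, Rarg, Slc38a6 and Rbm39 after dDAVP.

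At gene ends, the best-scoring C/EBP beta peaks found in both treatments were at Abhd11, Cotl1, Trib1, Rpia, Rbm39, Hmox1, Ndrg1, Aacs, Mcm3 and Rad23b. Hmox1 encodes heme oxygenase and had a vehicle score of 395, 44 bp from a gene end. The best-scoring dDAVP peaks without a vehicle peak were at Tomm6 (score 1396), Atp6v1f (1303), Prmt3 (1303), Taco1 (1211) and Pycr1 (1196), an enzyme of proline synthesis. These 5 scores all lay above the median of 1104 for dDAVP peaks that were shared.

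CREB1 and C/EBP beta occupied different parts of the genome relative to genes. CREB1 peaks gathered at gene ends, such as Nup214 with a centre 1 bp away after vehicle, a gene chosen after its value was seen. Among 783 placed vehicle peaks, 681 were within 1000 bp of a gene end (87.0%, 84.4 to 89.2), as were 356 of 404 after dDAVP (88.1%, 84.6 to 90.9). C/EBP beta peaks were mostly far from gene ends, like those at Cdkl4 and Rcn1. Of the C/EBP beta peaks, 49 of 209 after vehicle (23.4%, 18.2 to 29.6) and 476 of 2401 after dDAVP (19.8%, 18.3 to 21.5) were at a gene end.

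The CREB1 share was higher than the C/EBP beta share by 63.5 points after vehicle (Fisher's exact test, adjusted p = 3.81e-69) and by 68.3 points after dDAVP (adjusted exact p = 1.22e-158). Random placements gave 2.79% to 3.25%. Median distances to a gene end were 62 bp and 46 bp for CREB1 after vehicle and dDAVP, and 9057 bp and 11685 bp for C/EBP beta. Within genes but away from their ends lay 9.07% and 7.92% of CREB1 peaks, and 37.3% and 40.2% of C/EBP beta peaks. Between treatments the share at gene ends did not pass the test for CREB1 (1.15 points higher after dDAVP, adjusted exact p = 0.645) or for C/EBP beta (-3.62 points, adjusted exact p = 0.278). Nearly all peaks of the shorter list count on both sides here and at 500 bp below, so these p-values do not compare separate sets. Separate sets gave 88.4% for shared and 85.6% for other CREB1 vehicle peaks (Fisher's exact test, unadjusted p = 0.288). For shared and other C/EBP beta dDAVP peaks they gave 23.4% and 19.5% (unadjusted exact p = 0.174). At a distance of 500 bp the C/EBP beta difference was -6.64 points and passed (adjusted exact p = 0.0196; 0.0196 to 1 over the alternatives).

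**Figure D2:**
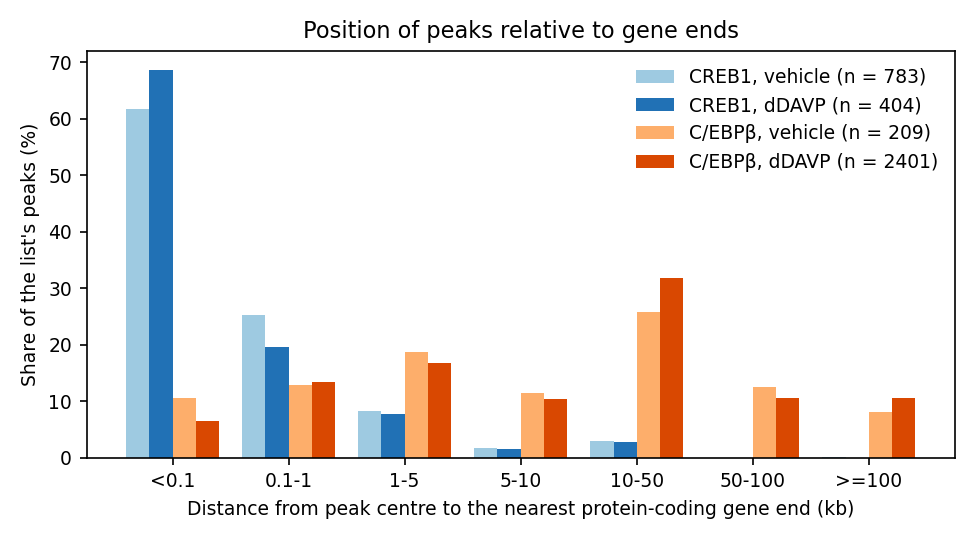
Bars show the share of each list's placed peaks, in percent, by distance from the peak centre to the nearest end of a protein-coding gene, in kb classes of unequal width. Below 0.1 kb lie 61.7% and 68.6% of CREB1 peaks, against 10.5% and 6.46% of C/EBP beta peaks, after vehicle and dDAVP.

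Gene lists set in advance were then compared with the peaks, to see which functions had a gene near a site. In all, 13 of the 60 pairs of a gene list and a peak list passed, all with more genes near a peak than other genes had. CREB1 peaks were near 1092 of 21631 genes after vehicle and 577 after dDAVP, and C/EBP beta peaks near 111 and 1084. The calls were 3 for CREB1 after vehicle, 1 for CREB1 after dDAVP, 2 for C/EBP beta after vehicle and 7 for C/EBP beta after dDAVP. Differences in list length set how many genes can pass, and changes of a gene list between treatments were not tested. The background was all other protein-coding genes, whether active in these cells or not. A preference for active genes was therefore not told apart from a preference for a function.

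Genes of the amino acid response driven by ATF4 were near C/EBP beta peaks in both treatments. After dDAVP 21 of 36 had a peak (58.3%), against 4.92% of other genes (odds ratio 27.0, adjusted p = 6.75e-17, Fisher's exact test). The odds ratio was 10.3 in the upper 50% of scores (8 of 36, adjusted exact p = 0.000274), 11.2 at 50000 bp and 32.0 at 1000 bp, and the call held in these. Peaks were centred within 31 bp of an end of Aldh18a1, Trib3, Iars, Nars, Gars and Cars. Of these, Iars, Nars, Gars and Cars encode aminoacyl-tRNA synthetases, Aldh18a1 an enzyme of proline synthesis and Trib3 a pseudokinase. After vehicle 4 of 36 had a C/EBP beta peak (adjusted exact p = 0.00102): Iars, Chac1, Ddit3 and Sars. The vehicle call was lost in the upper 50% of scores, with 1 of 36 genes (adjusted exact p = 0.301; 0.000162 to 0.301 over the alternatives, with odds ratios of 11.6 to 37.7).

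CREB1 peaks were near 3 of these 36 ATF4 pathway genes after vehicle, Atf4, Aars and Eprs (adjusted exact p = 0.884), and near Aars and Eprs after dDAVP (adjusted exact p = 0.643). Among genes near peaks of a single factor after vehicle, 3 of 1079 CREB1 genes and 4 of 98 C/EBP beta genes were in the list, which differed (Fisher's exact test, adjusted p = 0.0391 over 30 comparisons). After dDAVP these were 1 of 505 and 20 of 1012, and the difference missed the threshold (adjusted exact p = 0.0515).

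Collecting duct genes had C/EBP beta peaks after dDAVP at 8 of 36 (22.2% against 4.98% of other genes, odds ratio 5.45, adjusted exact p = 0.00334). The closest were at Ehf (16 bp), at Grhl2 (249 bp), which encodes an epithelial grainyhead factor, at Aqp2 (427 bp) and at Emx2 (1072 bp). Peaks at Fxyd4 (1569 bp), a regulator of the sodium pump, at Kcnj1 (2711 bp), and at Scnn1a (4799 bp), the alpha subunit of the epithelial sodium channel, were farther away. After vehicle Ehf and Kcnj1 had a C/EBP beta peak (2 of 36, adjusted exact p = 0.0550). CREB1 lists had 0 of 36 in each treatment (adjusted exact p = 0.643 and 1). At a distance of 1000 bp the C/EBP beta call after dDAVP was lost, with 3 of 36 genes (adjusted exact p = 0.214; 0.00478 to 0.214 over the alternatives, with odds ratios of 3.44 to 7.18).

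CREB target genes known from textbooks were near CREB1 peaks after vehicle at 7 of 37 (18.9% against 5.02%, odds ratio 4.41, adjusted exact p = 0.0134). Those were Ier2, Junb, Per1, Fos, Pcna, Hspa5 and Ccna2, the first 6 within 185 bp of a gene end. Fos, Pcna and Ccna2 had a CREB1 peak after dDAVP (3 of 37, adjusted exact p = 0.239). C/EBP beta peaks after dDAVP were near 7 of 37 as well (odds ratio 4.45, adjusted exact p = 0.0134), including Atf3, Cebpb, Per1, Ier2, Rgs2 and Hspa5, and near 0 of 37 after vehicle. Both calls were lost at 50000 bp, with adjusted exact p = 0.382 for CREB1 (0.00793 to 0.382 over the alternatives, odds ratios 1.93 to 5.72) and 0.633 for C/EBP beta (0.0218 to 0.633, odds ratios 1.38 to 6.13).

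In the list of cAMP and protein kinase A signalling, CREB1 peaks after vehicle were near Creb1, Prkaca, the catalytic subunit of the kinase, and Crebbp, a coactivator (3 of 35, adjusted exact p = 0.643). After dDAVP Crebbp alone had a CREB1 peak (1 of 35), and C/EBP beta peaks were near 0 of 35 in both treatments. The list passed in none of the 4 peak lists.

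Protein folding and ER stress genes passed in all 4 peak lists. CREB1 peaks after vehicle were near 7 of 27 (25.9%, odds ratio 6.62, adjusted exact p = 0.00334), among them Dnajb1, Hyou1, Dnajb9, Dnajb11, Hspa5 and Canx, which encode chaperones. After dDAVP CREB1 peaks were near Ppp1r15a, Dnajb11, Dnajb9 and Syvn1 (4 of 27, odds ratio 6.38, adjusted exact p = 0.0295). C/EBP beta peaks were near Herpud1 and Ddit3 after vehicle (2 of 27, adjusted exact p = 0.0421). After dDAVP they were near Atf6, Dnajb9 and Hspa5 too (5 of 27, odds ratio 4.32, adjusted exact p = 0.0465). The CREB1 vehicle call held in its 3 alternatives. The others were lost in at least 1, with adjusted exact p up to 0.0806 for CREB1 after dDAVP (from 0.0173; 3 of 27 genes and an odds ratio of 5.82 at 1000 bp), 1 for C/EBP beta after vehicle (from 0.0218) and 0.182 after dDAVP (from 0.00243). The C/EBP beta odds ratios ranged from 0 to 32.5 after vehicle and from 3.91 to 6.81 after dDAVP.

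Ribosomal protein genes were near CREB1 peaks after vehicle at 8 of 40 (20.0%, odds ratio 4.73, adjusted exact p = 0.00560). Centres were 43 to 76 bp from an end of Rpl13, Rps9, Rpl3, Rpl23 and Rps27. Rpl23, Rpl4 and Rpl18 kept a CREB1 peak after dDAVP (3 of 40, odds ratio 2.97, adjusted exact p = 0.271). Another set, the genes whose symbol is Rpl followed by a digit, was chosen after the data were seen. It passed in both CREB1 lists, with 11 of 53 after vehicle (adjusted exact p = 0.00372) and 8 of 53 after dDAVP (odds ratio 6.56, adjusted exact p = 0.00451). C/EBP beta peaks were near 2 of 40 after dDAVP, Rpl10a and Rpl13 (adjusted exact p = 1). At 50000 bp the CREB1 vehicle call was lost (adjusted exact p = 0.0871; 0.0113 to 0.0871 over the alternatives, with odds ratios of 2.66 to 4.32).

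Immediate early and AP-1 genes had C/EBP beta peaks after dDAVP at 8 of 32 (odds ratio 6.36, adjusted exact p = 0.00278), including Atf3, Maff, Fosl1, Ier2, Myc and Dusp5. Myc and Fosl2 had a C/EBP beta peak after vehicle (2 of 32, adjusted exact p = 0.0502). CREB1 peaks were near Ier2, Mafk, Junb and Fos after vehicle (4 of 32, adjusted exact p = 0.239) and near Fos after dDAVP (1 of 32, adjusted exact p = 1). Genes of the C/EBP family and of acute phase and cytokine responses had C/EBP beta peaks after dDAVP at 8 of 34 (odds ratio 5.87, adjusted exact p = 0.00329). Among them were Ptgs2 (cyclooxygenase), C3 (complement), Trib1, Il6ra, Lcn2 (lipocalin) and Cebpb. Trib1 and Ddit3 had a C/EBP beta peak after vehicle (2 of 34, adjusted exact p = 0.0526), and CREB1 lists had 0 of 34. In the upper 50% of scores both dDAVP calls were lost, with adjusted exact p = 0.0649 for immediate early genes (0.00535 to 0.0649 over the alternatives, odds ratios 3.34 to 5.75) and 0.0729 for acute phase genes (0.000535 to 0.0729, odds ratios 3.01 to 10.2).

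Circadian clock genes were near C/EBP beta peaks after dDAVP at 6 of 22 (27.3%, odds ratio 7.14, adjusted exact p = 0.00500). These were Ciart, Per1, Cry2, Bhlhe40, Nfil3 and Per2. Per1 was the single clock gene with a CREB1 peak, after vehicle (1 of 22, adjusted exact p = 1). The C/EBP beta call was lost at 1000 bp (adjusted exact p = 0.0780) and at 50000 bp (adjusted exact p = 0.120; 0.000625 to 0.120 over the alternatives, with odds ratios of 2.97 to 13.5).

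Glucocorticoid response genes passed in none of the 4 peak lists. C/EBP beta peaks after dDAVP were near Lcn2, Cebpb and Per1 (3 of 20, adjusted exact p = 0.239), and CREB1 peaks after vehicle near Per1 and Cdkn1a (2 of 20, adjusted exact p = 0.643). Genes of epithelial junctions and keratins had C/EBP beta peaks after dDAVP near Cldn8, Esrp2 and Cldn3 (3 of 29, adjusted exact p = 0.502). Markers of other kidney cells were checked as well. After dDAVP C/EBP beta peaks were near Insrr among 16 intercalated cell markers and near Slc34a3 among 18 proximal tubule markers (adjusted exact p = 1 for each). No peak of either factor was near the 14 markers of the thick limb and distal tubule or the 23 of endothelial, podocyte, stromal and immune cells. At most 5.05% of all protein-coding genes were near a peak in any list, so a lack of peaks in lists this short does not show depletion.

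**Figure D3:**
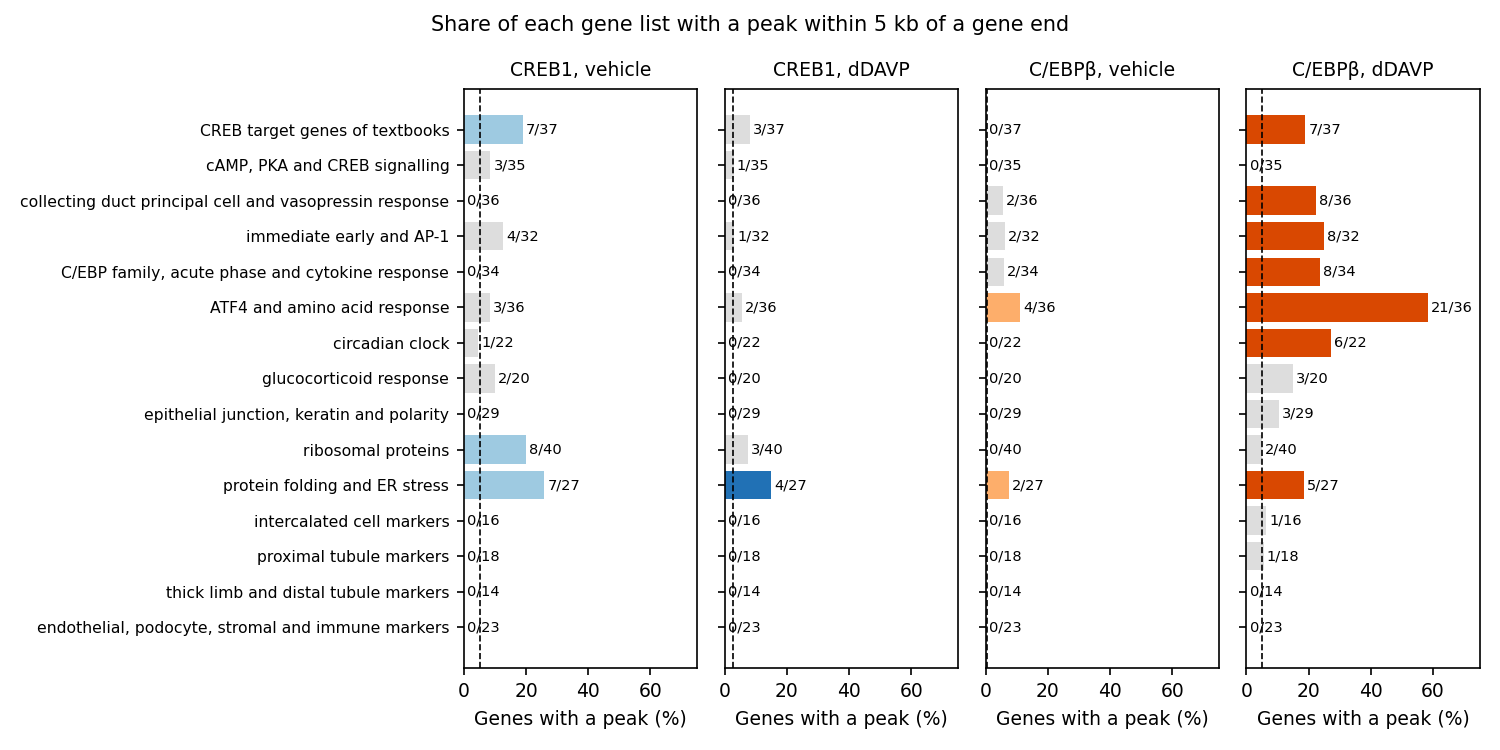
Bars show the percent of genes in each of 15 lists with a peak within 5000 bp of a gene end, in a panel per peak list. Coloured bars passed the test, grey bars did not, each bar carries its counts, and the dashed line is the share of all protein-coding genes. The longest bar, 21 of 36, is the ATF4 list in the C/EBP beta dDAVP panel.

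The lists were then compared between factors, to see whether CREB1 and C/EBP beta peaks coincided. After vehicle 5 CREB1 peaks overlapped a C/EBP beta peak, among them peaks nearest to Cenpl, Frmd8, Man1b1 and Spty2d1, genes chosen after their values were seen. After dDAVP 20 did, among them peaks at Csnk1g2, Oaz1, Dnajb9, Tomm6 and Ddx49. The Dnajb9 overlap was with a CREB1 peak on chromosome 12 from 44210142 to 44210285, 146 bp from an end of this chaperone gene.

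The vehicle overlap was 0.637% of 785 CREB1 peaks (0.272 to 1.48), against a random mean of 0.04 peaks. The dDAVP overlap was 4.93% of 406 (3.21 to 7.49), against a random mean of 0.24 peaks. In both, the permutation p was 0.001, the smallest possible. With CREB1 regions moved to random gene ends, added after seeing the data, the means were higher, at 0.66 peaks for vehicle and 2.29 for dDAVP (permutation p = 0.005 for each, the smallest possible over 200 moves). With the treatments crossed, 49 of 785 CREB1 vehicle peaks (6.24%) overlapped the C/EBP beta dDAVP list. Only 1 of 406 CREB1 dDAVP peaks (0.246%) overlapped the C/EBP beta vehicle list. The share was thus higher with the longer C/EBP beta list, whichever CREB1 list was used, and does not show more coincidence after dDAVP. The C/EBP beta lists differ in length. Reduced to its 406 best scores, the length of the CREB1 dDAVP list, the C/EBP beta dDAVP list gave an overlap of 1.48% (6 peaks, permutation p = 0.001). That cut list was still longer than the C/EBP beta vehicle list of 209 peaks, so 1.48% and 0.637% are not matched for length. With the upper 50% of scores the overlaps were 0.255% and 2.96%, and with gaps up to 1000 bp allowed the dDAVP overlap was 7.64%.

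A region at Man1b1, which encodes a mannosidase that trims glycoproteins in the secretory pathway, was the single region with a peak in all 4 lists. Its CREB1 vehicle peak lay on chromosome 2 from 25332396 to 25332794, with its centre 135 bp from a gene end. The number stayed at 1 when gaps up to 1000 bp were allowed and when centres within 200 bp were asked for.

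For the genes named in advance, distances to the nearest peak differed by factor and treatment. Aqp2 had its nearest CREB1 peak 141 kb away after vehicle and 504 kb after dDAVP, and its nearest C/EBP beta peak 2659 kb and 0.427 kb away. Creb1 had a CREB1 peak at 0.099 kb after vehicle and none within 9480 kb after dDAVP. Cebpb had C/EBP beta peaks at 143 kb and 0.259 kb, and CREB1 peaks at 674 kb in both treatments. For Per1 the distances were 0.101 and 86.6 kb for CREB1 and 965 and 0.272 kb for C/EBP beta.

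Nr4a1, an orphan nuclear receptor gene and textbook CREB target, had no peak closer than 702 kb in either CREB1 list and none closer than 95.8 kb in the C/EBP beta lists. Crem, which encodes a CREB relative, had its nearest peak 206 kb away, in the C/EBP beta dDAVP list. Sgk1, a kinase that regulates sodium transport, had its nearest peak 201 kb away in that list, and CREB1 peaks 8201 kb away in both treatments. Scnn1a had its nearest C/EBP beta peaks at 66.3 kb after vehicle and 4.80 kb after dDAVP, and its nearest CREB1 peaks at 275 kb and 5948 kb.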

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

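The values and tests in this part were chosen after the results were seen. The names of the C/EBP beta peaks, which no comparison above uses, number the peaks first called in replicate 1. The highest number was 2707 after dDAVP and 329 after vehicle. Thus at most 88.6% and 63.5% of the numbered replicate 1 peaks were kept in the deposited lists. This column stands out because it holds information on replicate 1 that the pooled positions do not give.

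For each antibody the longer list held nearly all of the shorter, for genes such as Fos and Trib1, and the direction was opposite for CREB1 and C/EBP beta. Loss of peaks through poorer replicate agreement after vehicle could have added to the C/EBP beta gap. The highest replicate 1 numbers left in the lists differed 8.23 times, which argues against it as the sole cause. These numbers are lower bounds on the replicate 1 calls, so such a loss is not excluded. Gains or losses unrelated to a site's strength are argued against. Of the 209 best-scoring C/EBP beta dDAVP peaks 26.8% lacked a vehicle peak, against 91.3% of all dDAVP peaks. Gains with dDAVP at sites weaker than those already present would give the same values and stay open. A candidate explanation is that the shorter list reached mainly the stronger sites of the longer. Shared peaks ranked above the others, with an area under the curve of 0.977 by score for C/EBP beta and 0.879 by width for CREB1. For C/EBP beta this is the same ranking as the percents above. For CREB1, width stood in for strength because its lists have no score, and whether width follows strength was not tested. Even so, 75 of the 242 best-scoring C/EBP beta dDAVP peaks had no vehicle peak. Of the 80 widest CREB1 vehicle peaks 6 had no dDAVP peak. A shorter list of mainly stronger sites could come from depth, yield or thresholds, or from a change in overall occupancy by dDAVP. No value in these lists separates these.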

How the results depend on the processing

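Random gene ends for the overlap of both factors and a background without Olfr, Vmn and Gm genes were chosen after seeing the data; the other alternatives were planned. In all, 27 results were computed under 105 alternative values. No paired analysis was possible because each group has a single pooled list, so no replicate could be matched or left out. The motif search was not run, nor its alternatives, and CREB1 lists could not be filtered by score, since they have none. For C/EBP beta, peaks in 1 treatment list alone could not be compared, because the vehicle list has 0 of its own. Unknown depth limits what a missing peak can show.

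Overlaps between treatments and between factors kept their side of the threshold in every alternative run, as did both differences between CREB1 and C/EBP beta at gene ends, and the peak counts and the Man1b1 region stayed within their limits. The CREB1 difference between treatments at gene ends turned to -10.6 points among peaks found in 1 treatment (adjusted exact p = 0.332), which has 8 peaks on the dDAVP side. For C/EBP beta it was -6.64 points at 500 bp (adjusted exact p = 0.0196), now past the threshold. In the upper 50% of scores it was 0.436 points (adjusted exact p = 1), turned in direction. The C/EBP beta lists share peaks, so these p-values do not compare separate sets, and the cause was not tested. Gene list calls fell from 13 to 8 at 50000 bp, and the cause was not tested. Of the 13 calls, 2 held in every alternative run for them, ATF4 genes with C/EBP beta after dDAVP and protein folding genes with CREB1 after vehicle. At 1000 bp 10 of 13 held, at 50000 bp 8, and with the smaller background 11. In the upper 50% of scores 4 of 9 held, and protein folding genes after vehicle had an odds ratio of 0 for C/EBP beta, turned in direction because the remaining peaks were near none of its 27 genes.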

Other observations

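The groups and tests in this part were chosen after the data were seen. Beyond the gene lists, genes that share the letters before the first digit of their symbol, called a stem here, were tested as groups, over 660 pairs of a stem with at least 15 genes and a peak list. CREB1 peaks after vehicle were near 8 of 16 genes of the Trmt stem, named for tRNA methyltransferases (odds ratio 18.9, Fisher's exact test, adjusted p = 3.47e-05), such as Trmt61a, Trmt5 and Trmt10c. RNA helicase genes of the Ddx stem had 9 of 36 (adjusted exact p = 0.00372), general transcription factor genes of the Gtf stem 6 of 23 (adjusted exact p = 0.0288) and genes of the Rab stem 12 of 69 (adjusted exact p = 0.00745). Ribosomal protein genes of the Rpl stem had 11 of 53 after vehicle (adjusted exact p = 0.00372) and 8 of 53 after dDAVP (adjusted exact p = 0.00451), including Rpl21, Rpl24, Rpl34 and Rpl41 in both. After dDAVP 5 of 16 Trmt genes (adjusted exact p = 0.00372) and 6 of 36 Ddx genes (adjusted exact p = 0.0143) were near a CREB1 peak. Olfactory receptor genes of the Olfr stem had 0 of 1110 near a peak in both CREB1 lists and in the C/EBP beta dDAVP list. Gene activity was not measured here, so whether these stems differ from other active genes was not tested.

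CREB1 peaks at gene ends were often near more than 1 gene. After vehicle 177 of 681 had at least 2 genes with an end within 1000 bp (26.0%), and after dDAVP 101 of 356 (28.4%). Among C/EBP beta peaks at gene ends after dDAVP this was 71 of 476 (14.9%), and at random gene ends 563 of 4000 (14.1%). The CREB1 and C/EBP beta dDAVP shares differed (Fisher's exact test, unadjusted p = 2.67e-06). The random ends mixed starts and other ends of genes, whether active or not. They are therefore no baseline for a factor that prefers active gene starts.

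Some genes were the nearest gene of several C/EBP beta peaks after dDAVP, which was not compared with chance or with the spacing of genes. Myc, the growth regulator, was the nearest gene of 10 peaks over 712 kb of chromosome 15, from 61983450 to 62695169. Gm40363 was nearest to 6 peaks over 78.2 kb of chromosome 6. Trib1, over 175 kb, and Cited2, over 855 kb, were among 7 genes nearest to 5 peaks each. On chromosome 17, 3 of the C/EBP beta vehicle peaks with ranks 3, 4 and 12 by score lay between 6406895 and 6678535. This stretch holds the paralogs Dynlt1b, Dynlt1c and Dynlt1f, with Dynlt1a before it. The peak of rank 4 lay inside Sytl3, past Dynlt1f.

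Peaks of both factors were sparse on chromosomes 7 and X, and less so on chromosome 4. There the ratios defined next were 0.575 and 0.615 for CREB1 and 0.446 and 0.517 for C/EBP beta, after vehicle and dDAVP. Other chromosomes were rich in peaks of both factors. In the same order the ratios were 2.12, 2.48, 2.09 and 1.99 on chromosome 12, and 1.89, 2.17, 1.30 and 1.66 on chromosome 19. Peaks per coding gene, leaving out Olfr, Vmn and Gm genes, on chromosome 7 were 0.335 times the genome mean in the CREB1 vehicle list and 0.323 times in the C/EBP beta dDAVP list, and on X 0 and 0.191 times, while chromosome 18 had 0.250 times for CREB1 after vehicle, 0.832 times for C/EBP beta after dDAVP and 0.375 times, from 2 peaks, for C/EBP beta after vehicle. Gene number does not account for this, since these ratios are per gene, nor, in the C/EBP beta dDAVP list, do rows lost after numbering on chromosomes 7 and 18, where at least 86.1% and 96.2% of the numbers between the neighbouring chromosomes were kept; lost rows stay open for X, which holds the last numbers, and for CREB1, whose peaks have none. Chromosome copy number of this line is a candidate explanation that a relation between peak lists cannot test. Across 20 chromosomes the CREB1 vehicle and C/EBP beta dDAVP ratios went together (Pearson r = 0.818, permutation p = 3e-05, adjusted p = 5e-05 over 3 relations). Spearman rho was 0.699 (permutation p = 0.0009, adjusted p = 0.001), and r was 0.688 without 12 and X. Both ratios are per gene, and a shared denominator can raise r by itself. With C/EBP beta dDAVP peaks more than 1000 bp from a gene end taken per Mb instead, r was 0.851 (permutation p = 1e-05, adjusted p = 3e-05). Chromosome 18 departed from the relation, low for CREB1 and nearer the mean for C/EBP beta after dDAVP. Gene activity that differs by chromosome could give the same relation, so copy number and gene activity both stay open, as input coverage was not used here.

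CREB1 and C/EBP beta peaks coincided at genes such as Dnajb9 and Oaz1. Whether this follows because both factors sit at gene ends was tested by moving CREB1 regions to random gene ends of the same chromosome. After dDAVP 200 such moves gave a mean of 2.29 overlaps and at most 10, against 20 observed, or 4.93% of CREB1 peaks (permutation p = 0.005, the smallest possible). Random ends of all coding genes, starts and other ends alike, thus gave fewer overlaps than observed. Without strand, a preference of both factors for gene starts could not be tested and stays open. Active or open gene ends may still be favoured by both factors, or by any antibody, and this was not tested.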
